A study of Mus musculus with 24 samples.

How the data were processed

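RNA of 24 mouse bladder samples was sequenced on an Illumina HiSeq instrument from poly-A selected TruSeq libraries. The deposited table holds 1 column per sample and 24256 genes by symbol. Its unit is recorded as signal: per the labels the authors used STAR, featureCounts and DESeq2 (versions, settings, genome build and annotation not given) and deposited normalized counts, which are gene read counts divided by 1 factor per sample. This was checked on the values. In each column they were whole multiples of 1 step (100% of values within 0.001 of a whole read), which gave back the reads per gene. Size factors computed with DESeq2 from these reads were 0.999 to 1.00 times the deposited scaling. In 2 libraries the step is so near 1 that a simple test for whole reads cannot tell reads from scaled values, although the multiples hold there too. The libraries held 8958512 to 13337322 reads in genes, and a value of 1 read was 0.799 to 1.30 normalized counts. No molecular identifiers were used, so intervals cover counting error only. The lowest chi-square per degree of freedom between replicates was 6.26, so the spread between mice was well above counting error.

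Scaling by median ratios assumes that most genes do not change. Between tumours and normal epithelium most genes did, so scaling to equal totals and quantile normalization were tried as well. Tumour RNA can hold that of several cell types, and poly-A selection leaves out RNA without a tail. Counts per gene do not separate isoforms, nor transcripts that lack a floxed exon.

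Samples were grouped by genotype and treatment as labelled. The groups, comparisons, tests, gene lists, rule for named genes and alternatives were chosen before the data were examined, except where the text says that a choice was made after. Genes with a normalized count of at least 10 in at least 4 samples were tested (15308). The test was limma (version 3.58.1, in R 4.3.3) on log2(normalized count + 1), with empirical Bayes moderation, trend and robust settings, 1 fit over all 24 samples with a coefficient per group and sex as labelled as a covariate. P values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons at 0.05. All tests were two-sided unless stated. Cdkn2a, Trp53 and Pten were compared with exact two-sided permutation tests of the difference in mean log2 value, adjusted over 18 tests.

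A set of 34 gene lists (525 members) was fixed. Of these members 3 (Trac, Ighm and Ly6g) are not in the table, and 4 were matched by a synonym (Adgre1 as Emr1, Epb42 as Epb4.2, Fcmr as Faim3, Jchain as Igj). Lists with at least 5 measured members, 31 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Camera compares a list with other genes, while fry tests whether its genes move, on balance, in 1 direction. Members were also counted after adjustment over the list alone. One list served to check the sex labels.

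Named genes were chosen by rule: Cdkn2a, Trp53 and Pten; among genes past the threshold with an absolute log2 fold change of at least 1, a mean of at least 100 in the higher group and no overlap of the sample ranges, the 10 largest rises and 10 largest falls; up to 4 members of each list with the smallest p; and, where fewer than 5 genes passed in a direction, the 5 with the smallest p. Predicted genes, pseudogenes, receptor segments and sex-linked genes were left out of the second part. List members named only as exceptions to their list's direction were chosen after their values were seen. A gene with no reads in a group is given as a bound at a floor of 3 reads over the group, and one with 1 to 3 reads as a ratio with its exact 95% counting interval.

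Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, no sex covariate, only the groups compared in the fit, scaling to equal totals, quantile normalization, RNA integrity or age as covariates, array weights, edgeR quasi-likelihood with TMM factors (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, and the omission of each library. A sex term taken from tumours only, a fit without WT epithelium and list medians with single libraries left out were added after seeing the data. Each comparison was repeated on 100 splits of its samples, the real one included. The agreement of the cisplatin responses, from a fit of the tumour groups alone with sex as a covariate, was set against 100 assignments of treatment within genotype.

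The method was tested on simulated data with the group sizes used here. It found 42 to 59% of genes changed 2-fold and 85 to 91% of those changed 4-fold across 6 comparisons, with 6 to 16 false calls in each. All groups were simulated with the same spread per gene. The real median SD was 0.179 in WT epithelium and 0.381 to 0.424 in tumour groups, so these rates need not hold for comparisons among tumours. A shifted mitosis list was called and 0 of 30 other lists. Genes were simulated independently, so this does not show how often lists of correlated genes are called without a change. Other splits of the real samples gave medians of 6 to 12 lists past the threshold. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6. No sample was left out. Raw reads were not processed again, and isoforms were not examined, since the table does not give them. The table gives no positions. The order of genes along chromosomes, used once in the closing section, was taken from the RefSeq annotation by symbol.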

Results

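RNA was measured in 24 bladder samples from mice by sequencing of poly-A selected total RNA. Tumours were induced by putting an adenovirus that carries Cre recombinase into the bladder lumen, where Cre deletes floxed genes. DKO mice carried floxed alleles of p53 and Pten with intact Arf. TKO mice carried floxed Arf as well. Tumour-bearing mice were given vehicle or cisplatin, a drug that crosslinks DNA, at 4 mg/kg each week. The 5 groups were DKO vehicle (n = 6), TKO vehicle (n = 4), DKO cisplatin (n = 4), TKO cisplatin (n = 5) and normal bladder epithelium of wild-type mice (WT epithelium, n = 5). The stated question of the series is what ARF, a tumour suppressor made from the Cdkn2a gene, does in the response to chemotherapy. WT mice were 3 to 4 months old and mice with tumours 5 to 8 months. RNA integrity numbers were 8.6 to 9.7 in WT epithelium and 9 to 10 in tumours. The libraries held 8958512 to 13337322 reads counted in genes, and 1 read stood for a normalized count of 0.799 to 1.30. Of 24256 genes, 15308 were abundant enough to test. The genome build and annotation are not stated, so genes are given by symbol without coordinates. Intervals and floors cover counting error only.

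WT epithelium and tumours lay on opposite sides of the first principal component, which held 59.7% of the variance among tested genes, against 6.73% for the second. TKO cisplatin replicate 4 was the tumour nearest to WT epithelium on it. Replicates of WT epithelium were more alike than tumours: the median within-group SD was 0.179 on the log2 scale in WT epithelium and 0.381 to 0.424 in the 4 tumour groups. DKO cisplatin libraries all came from females, and 4 of the 5 TKO cisplatin libraries from males.

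Ddx3y, a Y-linked gene, went with the sex label in all 19 tumours and against it in all 5 WT epithelium libraries. The 2 WT libraries labelled female had Ddx3y at 1112 to 1151 normalized counts and Xist, made from the inactive X chromosome, at 57.4 to 61.4. In the 3 WT libraries labelled male, Ddx3y was at 0 to 2.03 and Xist at 25242 to 26917. With the sex term taken from tumours only, an alternative added after seeing the data, 9629 genes differed between DKO vehicle and WT epithelium and 8828 between TKO vehicle and WT epithelium. Among tumours it gave 9 genes for TKO against DKO vehicle (13 in the main fit) and 2 for TKO against DKO with cisplatin (2). For cisplatin against vehicle it gave 321 in DKO (371) and 323 in TKO (260). The main fit used the sex labels as given, so its p values rest on labels that Ddx3y goes against in WT epithelium. List tests and omissions of single libraries were not repeated with the sex term from tumours only. TKO cisplatin replicate 4, labelled male, had Ddx3y at 796 and Xist at 2912, where the highest other male tumour had Xist at 481.

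**Figure D1:**
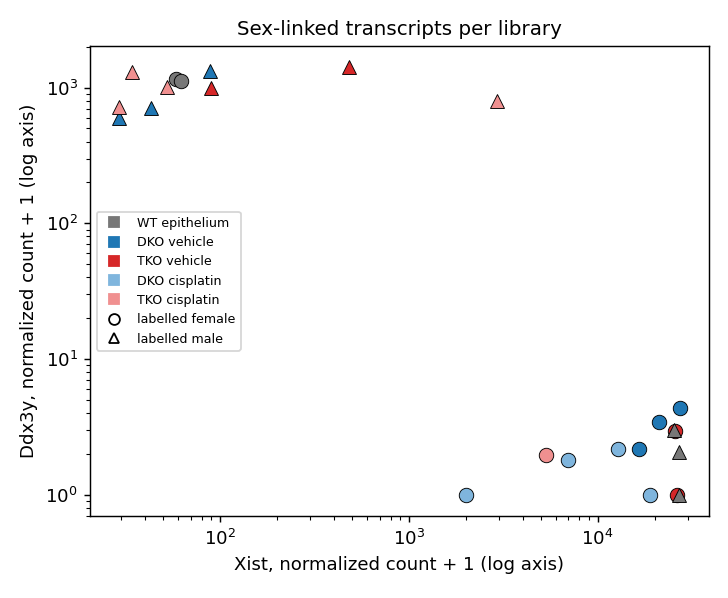
Normalized count + 1 of Xist (x axis, log) against Ddx3y (y axis, log) in each of the 24 libraries, with colours for the 5 groups and shapes for the sex label. The 3 WT libraries labelled male lie at Xist 25242 to 26917, and the 2 labelled female at Ddx3y 1112 to 1151.

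The floxed genes were compared first, with exact two-sided permutation tests adjusted over 18 comparisons. Trp53, which encodes p53, fell in all 4 tumour groups, from 667 ± 29.5 normalized counts (SD, n = 5) in WT epithelium to 246 ± 50.4 in DKO vehicle (n = 6), 164 ± 35.3 in TKO vehicle (n = 4), 265 ± 85.9 in DKO cisplatin (n = 4) and 234 ± 109.9 in TKO cisplatin (n = 5). Cdkn2a rose in the same 4 groups, from 29.6 ± 32.2 to 2727 ± 924, 2944 ± 475, 1980.4 ± 434 and 2592 ± 912. Every tumour library lay beyond every WT library for both genes (adjusted exact p = 0.0179 each). Pten fell in no tumour group. It was at 1046 ± 90.3 in WT epithelium, 967 ± 145 in DKO vehicle and 1239.8 ± 293 in TKO vehicle (adjusted exact p = 0.359 and 0.341), and rose to 1338 ± 81.7 in DKO cisplatin and 1523 ± 411 in TKO cisplatin (adjusted exact p = 0.0286 each). Between TKO and DKO tumours, Cdkn2a did not differ beyond the replicate spread with vehicle (exact p = 0.557) or cisplatin (exact p = 0.429). Trp53 was lower in TKO than in DKO vehicle tumours before adjustment (exact p = 0.0333) and not after it (0.0545), and Pten did not pass in either comparison of the genotypes (adjusted exact p = 0.114 with vehicle and 0.557 with cisplatin). Counts are per gene, so reads from Arf and from Ink4a, the other product of Cdkn2a, are not separated, and neither are transcripts that lack the floxed exons.

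**Figure D2:**
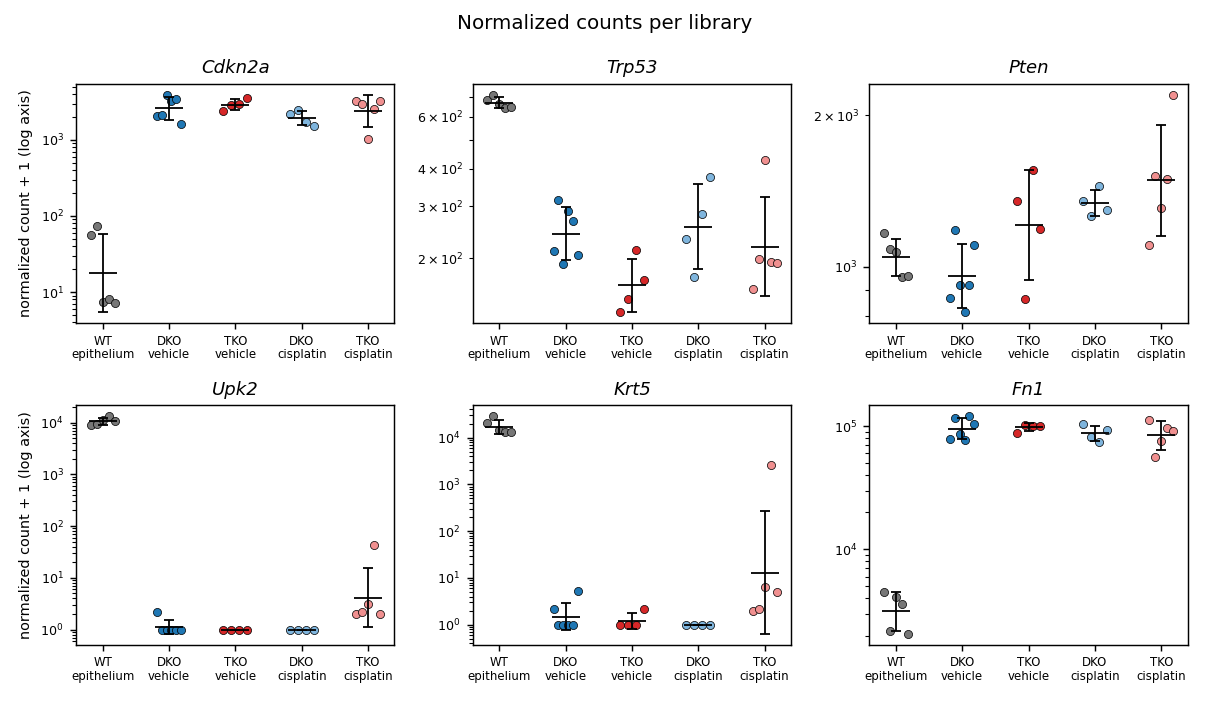
Normalized count + 1 (log axis) of Cdkn2a, Trp53, Pten, Upk2, Krt5 and Fn1 in each library of the 5 groups, where points are libraries and bars are the mean and SD of log2(normalized count + 1). Cdkn2a means were 1980.4 to 2944 in tumour groups and 29.6 in WT epithelium.

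Vehicle-treated tumours were compared with WT epithelium to ask what distinguishes tumours of each genotype from normal tissue. All 20 measured genes of urothelial differentiation fell in both genotypes, with a median log2 fold change of -9.34 in DKO and -10.03 in TKO tumours. They include uroplakins, which form the plaques of the apical membrane. Upk1a went from 32469.6 ± 3973 normalized counts in WT epithelium (SD, n = 5) to 5.98 ± 3.61 in DKO (n = 6) and 9.89 ± 10.5 in TKO tumours (n = 4). Upk3a was 128000 times lower in DKO tumours (95% counting interval 22900 to 5050000). Upk2 had no reads in TKO tumours and was at least 14800-fold lower, at a floor of 3 reads over the group. The fall was less deep for other uroplakins. Over vehicle and cisplatin tumours together, without TKO cisplatin replicate 4, the median was 453 for Upk1b and 349 for Upk3b. Their means in WT epithelium were 29736 and 4690. Other genes with very low levels were Sptssb (127000 times lower in DKO, 22900 to 5030000), Gsdmc2 (at least 18200-fold lower in DKO) and Fer1l4 (at least 9260-fold lower in TKO). Among 14 genes of basal and keratinocyte-like cells, 9 fell in each genotype, including Krt5 and Trp63, a transcription factor of basal cells (4888 ± 469 in WT epithelium, 16.3 ± 10.4 in DKO, 20.8 ± 22.5 in TKO). Egfr and Cdh3 of that list rose in both genotypes and Cd44 in DKO. Of 11 squamous cornification genes, 7 fell in DKO (Ivl, Krt1, Sprr1a and others; median log2 fold change -2.12, or -2.52 with genes at the floor set to their bound). In TKO tumours 6 fell and Sprr2d rose. By camera with a preset correlation, adjusted p was 9.16e-12 in DKO and 3.77e-13 in TKO for the urothelial list (adjusted p = 0.146 and 0.141 with an estimated correlation), and 0.0276 and 0.013 for the basal list (adjusted p = 0.471 and 0.476 with an estimated correlation). The squamous list passed in DKO (0.0247; adjusted p = 0.471 with an estimated correlation) and not in TKO (0.0592). The counts for these 3 lists were the same adjusted over the list alone.

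Genes of cell division rose together in the vehicle tumours. All 20 mitosis genes rose in both genotypes, with medians of 4.98 in DKO and 5.11 in TKO on the log2 scale. Top2a, the topoisomerase of dividing cells, went from 87.8 ± 34.3 (SD, n = 5) to 2870.1 ± 964 in DKO (n = 6) and 2924 ± 834 in TKO (n = 4), and Cdk1, the kinase that drives entry into mitosis, from 12.9 ± 9.33 to 675 ± 235 and 758 ± 209. Of 22 DNA replication genes, 22 rose in DKO and 20 in TKO, among them E2f1 (49.3 ± 5.75 to 489.7 ± 117 and 452 ± 129). Genes for making ribosomes followed, with 14 of 18 higher in DKO and 11 in TKO (medians 0.78 and 0.76). In the list for the stress of protein folding, 9 of 13 rose in DKO (10 adjusted over the list alone) and 10 in TKO, including the chaperone Hspa5, while Herpud1 fell in both. The other counts here were the same adjusted over the list alone. For mitosis, DNA replication, ribosome biogenesis and protein folding, the camera adjusted p in DKO was 2.89e-14, 1.01e-09, 0.00181 and 0.0136 (adjusted p = 0.217, 0.265, 0.50 and 0.478 with an estimated correlation). In TKO it was 3.91e-15, 1.32e-09, 0.00451 and 0.00533 (adjusted p = 0.191, 0.271, 0.515 and 0.489 with an estimated correlation).

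Mesenchymal and matrix genes rose as well. Of 15 genes of the mesenchymal transition, 11 rose in DKO and 10 in TKO (11 adjusted over the list alone), with medians of 2.49 and 1.99. Fn1, fibronectin, went from 3296 ± 1119 normalized counts (SD, n = 5) to 96999 ± 18858 in DKO (n = 6) and 98152 ± 6536 in TKO (n = 4), and Vim, an intermediate filament of mesenchymal cells, from 4386 ± 738 to 27392 ± 8711 and 25448 ± 8074. Of 12 genes for matrix proteases and their regulators, 10 rose in each genotype (medians 4.77 and 4.64), and Mmp12 fell in TKO. The inhibitor Timp1 was at 54.4 ± 23.5, 5208 ± 2491 and 1769 ± 543. Of 14 fibroblast markers, 11 rose in DKO and 10 in TKO (medians 3.04 and 3.43), including the collagen gene Col1a1 (12561 ± 5225, 253104 ± 130231 and 198011 ± 57068), while Fbln1 fell in both. Genes with the largest rises in DKO also included Wt1, a transcription factor (5040 times higher, 95% counting interval 904 to 199000), the stromelysin Mmp3 (11400 times, 3150 to 93900), Fbn2, Tnmd, Tnn and Thbs4. In TKO, Wt1 was 10300 times higher (1850 to 407000). By camera the mesenchymal list had an adjusted p of 2.21e-06 in DKO (adjusted p = 0.0441 with an estimated correlation) and 6.02e-06 in TKO (adjusted p = 0.0603 with an estimated correlation). The proteases had 0.000136 and 0.000308 (adjusted p = 0.0702 and 0.0962 with an estimated correlation), and fibroblasts 0.000513 and 0.000533 (adjusted p = 0.161 and 0.156 with an estimated correlation). Except where given, counts were the same adjusted over the list alone.

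Markers of myeloid cells and their signals were higher in vehicle tumours than in WT epithelium. Of 16 macrophage markers, 13 rose in DKO and 10 in TKO (11 adjusted over the list alone), including Csf1r, the receptor of a macrophage growth factor (629.6 ± 184 in WT epithelium, SD, n = 5; 5387 ± 2150.2 in DKO, n = 6; 4094 ± 1695 in TKO, n = 4). Of 11 neutrophil markers, 9 rose in DKO and 6 in TKO (7 adjusted over the list alone). Their medians were 3.43 and 2.32 as fitted, and 4.31 and 3.05 with genes at the floor set to their bound. Of 17 inflammatory cytokines, 12 rose in DKO and 11 in TKO (12 adjusted over the list alone), such as the chemokine gene Ccl2 (10.3 ± 3.1, 949 ± 548 and 499.5 ± 307), and Il1a and Csf3 fell in TKO. Of 25 interferon response genes, 14 rose in DKO and 15 in TKO (16 adjusted over the list alone in each). Except where given, counts were the same adjusted over the list alone. For macrophages, neutrophils, cytokines and interferon response, the camera adjusted p in DKO was 0.000298, 0.00157, 0.00141 and 0.00779 (adjusted p = 0.471, 0.471, 0.471 and 0.728 with an estimated correlation). In TKO it was 0.00357, 0.0155, 0.00738 and 0.00357 (adjusted p = 0.515, 0.515, 0.515 and 0.651 with an estimated correlation).

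Targets of p53 fell along with Trp53. Of 22 such genes, 14 fell and 2 rose in DKO, and 12 fell and 2 rose in TKO, with medians of -0.85 and -0.82 (-0.54 in TKO without TKO vehicle replicate 4). Perp, a desmosome gene, went from 7682 ± 957 (SD, n = 5) to 5.25 ± 2.41 in DKO (n = 6) and 14.1 ± 9.46 in TKO (n = 4), and Ei24 from 2932 ± 287 to 727 ± 103 and 798 ± 113. Those that rose in both genotypes were Gdf15, a secreted stress factor, and Tnfrsf10b, a death receptor. Of 14 targets of NRF2, the regulator of the antioxidant response, 9 fell and 2 rose (Srxn1 and Hmox1) in each genotype, with medians of -1.59 and -1.52. Nqo1, a quinone reductase, was at 2333 ± 219, 96.5 ± 48.9 and 154 ± 182. The counts were the same adjusted over the list alone. The camera adjusted p was 0.00655 in DKO and 0.0102 in TKO for p53 targets (adjusted p = 0.146 and 0.156 with an estimated correlation), and 0.00655 and 0.00738 for NRF2 targets (adjusted p = 0.471 and 0.476 with an estimated correlation).

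Across all genes, limma found 9565 that differed between DKO vehicle tumours and WT epithelium, 4607 higher and 4958 lower, of which 6102 by at least 2-fold. For TKO vehicle tumours it found 8722, 4223 higher and 4499 lower, of which 5776 by at least 2-fold. Which direction had more genes depended on the method. In DKO 5179 were higher and 4552 lower under quantile normalization, 5002 and 4527 by edgeR, and 4959 and 4809 by DESeq2, while scaling to equal totals gave 4192 and 5282. In TKO these pairs were 4741 and 4171, 4582 and 4149, 4641 and 4362, and 3866 and 4826. All 80 named genes past the threshold in DKO and all 76 in TKO stayed past it whichever library was left out, and so did the list calls. Most named genes were chosen for large changes or small p, so this does not show how stable the other calls are. Under quantile normalization the median log2 fold change of all genes in the DKO comparison moved from -0.03 to 0.08. A total of 3803 genes were higher and 4133 lower in both genotypes, against 1271 and 1457 had the 2 sets been independent, and 2 genes went in opposite directions. Both comparisons use the same WT libraries. With those libraries divided between the comparisons, 2885 genes were higher and 3122 lower in both, and fold changes correlated across genes at r = 0.960. In 20 simulated data sets without change in either genotype, 0 genes were shared, yet fold changes correlated at a median r of 0.496 through the shared WT libraries. With no changed genes to call, these data sets do not show how many shared genes the WT libraries add to the real counts. WT samples were epithelium and came from younger mice than the tumours, so age and cell content are not separated from tumour state in these values.

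**Figure D3:**
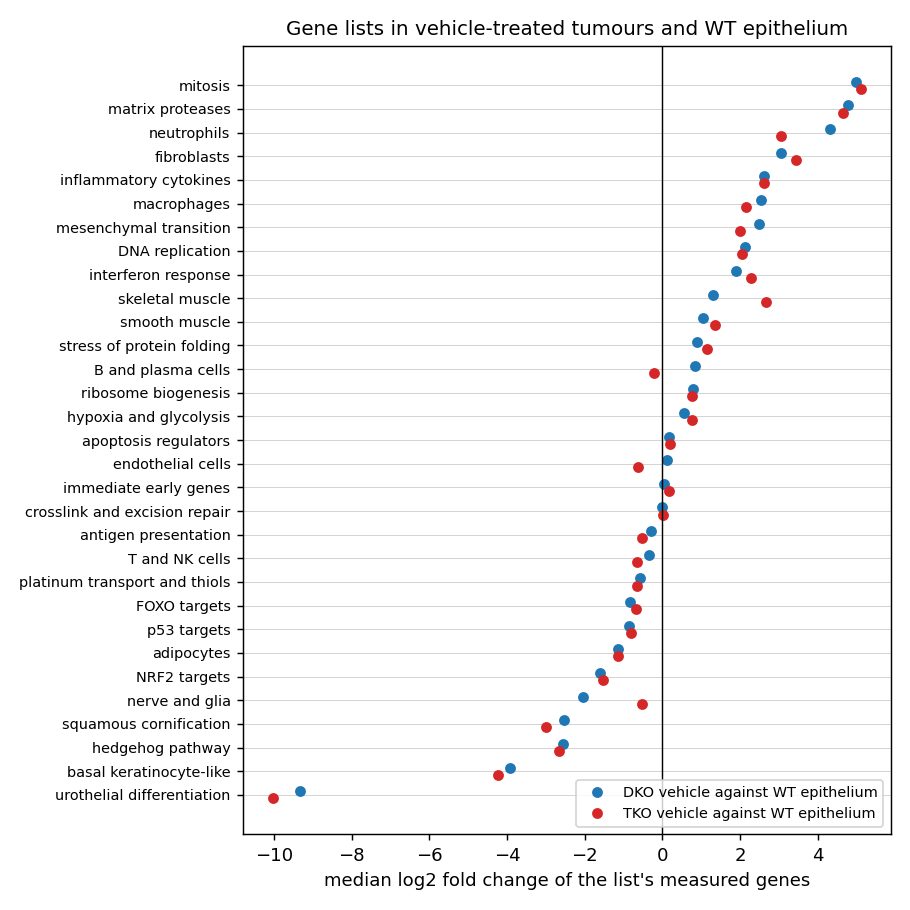
Median log2 fold change against WT epithelium (x axis) of each of the 31 tested gene lists (y axis), for DKO vehicle and TKO vehicle tumours, with genes at the floor set to their bound. The urothelial list lies at -9.34 and -10.03 and the mitosis list at 4.98 and 5.11.

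TKO and DKO tumours given vehicle were compared to ask what floxed Arf alleles add in untreated tumours. Few genes differed. Npy, which encodes neuropeptide Y, fell most among named genes, from 810.4 ± 489 normalized counts in DKO (SD, n = 6) to 38 ± 22.1 in TKO tumours (n = 4), a log2 fold change of -4.28. Pdlim2, an adaptor of the cytoskeleton, fell from 541 ± 130.1 to 221 ± 32.4. Klhl23 rose from 32.7 ± 14.6 to 122 ± 22.4, D2hgdh from 49.2 ± 9.33 to 119 ± 12, Rps3a1, a ribosomal protein gene, from 3058 ± 333 to 7081 ± 1243, and Clstn1 from 804 ± 219 to 1627 ± 329.5. Others past the threshold, named after their values were seen, were Gm13154, Gm4737, Glrp1 and Oxct1, which rose, and Atp10d, Ccdc85c and Pcdhgc4, which fell.

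By limma, 13 genes differed between the vehicle tumours of the 2 genotypes, 8 higher and 5 lower in TKO, and 1432 had an unadjusted p under 0.05 where 765.4 would be expected by chance. DESeq2 called 204. The count was 7 with a filter of 50, 6 with only the groups compared in the fit and 3 with array weights. It was 37 without DKO vehicle replicate 1, 8 without replicate 3, 7 without replicate 4 and 5 without replicate 5, and 8, 2 and 5 without TKO vehicle replicates 1, 3 and 4. Of the 6 named genes, only Npy (adjusted p = 0.00279) stayed past the threshold whichever library was left out. The other 5 were lost in at least 1 omission. Omitting TKO vehicle replicate 1 or 3 lost all 5. Omitting TKO vehicle replicate 2 or 4 or DKO vehicle replicate 3 or 5 lost 4 of them, DKO vehicle replicate 6 lost 3, and replicate 2 or 4 lost 2. With array weights only Npy of the 6 passed. With only the groups compared, Clstn1, D2hgdh, Klhl23 and Pdlim2 did not pass. With WT epithelium left out, Clstn1, Klhl23 and Rps3a1 did not. D2hgdh also did not pass with the sex term taken from tumours only or under quantile normalization.

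No member of any of the 31 tested lists passed the threshold over all genes in this comparison. Adjusted over the list alone, 1 squamous and 1 p53 target gene were higher and 1 matrix protease lower. By camera, endothelial markers were lower in TKO (13 genes, median -0.75, adjusted p = 0.000372; adjusted p = 0.865 with an estimated correlation) and skeletal muscle genes higher (10 genes, median 1.86 and 1.11 without TKO vehicle replicate 3, adjusted p = 4.72e-05; adjusted p = 0.865 with an estimated correlation), and both passed whichever library was left out. The mean log2 level of the skeletal muscle list was 6.78 and 7.58 in TKO vehicle replicates 2 and 3. It was 3.45 and 4.07 in replicates 1 and 4, and 2.86 to 5.12 in DKO vehicle libraries. Neutrophils (0.0019), macrophages (0.0287) and cytokines (0.0422) also passed as lower, and nerve and glia (0.0375) and smooth muscle (0.0422) as higher. Their adjusted p was 0.865 to 0.911 with an estimated correlation, and without TKO vehicle replicate 4 none of these 5 passed (0.108 to 0.843). Cytokines were also lost without DKO vehicle replicate 3, 4 or 5 or TKO vehicle replicate 2 or 3 (0.0558 to 0.214), macrophages without DKO vehicle replicate 3, 5 or 6 or TKO vehicle replicate 2 (0.0702 to 0.263), and nerve and glia without DKO vehicle replicate 2 or 6 or TKO vehicle replicate 2 (0.0558 to 0.142). Smooth muscle was also lost without DKO vehicle replicate 1, 2, 4, 5 or 6 or TKO vehicle replicate 1 (0.0556 to 0.170).

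Cisplatin was compared with vehicle in DKO tumours to ask what the drug changes where Arf is intact. Of 22 targets of p53, 4 rose (6 adjusted over the list alone) and none fell. By camera the list was higher (adjusted p = 0.000416; adjusted p = 0.0567 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, went from 416 ± 154 normalized counts with vehicle (SD, n = 6) to 1497 ± 481 with cisplatin (n = 4), a log2 fold change of 1.89. Mdm2, the ubiquitin ligase of p53, rose from 566 ± 81.9 to 922 ± 188, and Trp53inp1 and Bbc3 rose too. Among 17 genes of platinum transport and thiols, 3 rose (3 adjusted over the list alone), including the metallothionein genes Mt1 and Mt2 (Mt2 from 531 ± 340.4 to 2385 ± 631). Of 14 NRF2 targets 1 rose (2 adjusted over the list alone): Gclc, for glutathione synthesis, went from 287 ± 41.8 to 866 ± 222. In the list for DNA replication, Rrm2, a ribonucleotide reductase subunit, rose and Pola1, a DNA polymerase subunit, fell (adjusted over the list alone, 1 rose and 6 fell), and the median of its 22 genes was -0.60.

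Among named genes outside the lists, Armcx2 fell from 1353 ± 252 (SD, n = 6) to 454 ± 118 (n = 4), Dzip3 from 588 ± 123 to 228 ± 85.3, Pdlim2 from 541 ± 130.1 to 199 ± 44.5, Enpep, an aminopeptidase, from 336 ± 196 to 64.5 ± 30.1, and Wnt5a, a Wnt ligand, from 1688 ± 418 to 689 ± 346. Pdlim2 was also lower in TKO than in DKO vehicle tumours, and both calls use the same DKO vehicle libraries. It was at 221 ± 32.4 in TKO vehicle and 260 ± 71.5 in TKO cisplatin tumours. The microglia and macrophage genes Fcrls and Cx3cr1 fell from 574 ± 296 to 55.2 ± 28 and from 1334 ± 635 to 160.3 ± 156. Chil3, a chitinase-like protein of myeloid cells, rose from 87.1 ± 58.4 to 1216 ± 842, and Clec4d, a C-type lectin of myeloid cells, from 165 ± 64.3 to 1129 ± 757.

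Limma called 371 genes in this comparison, 223 higher and 148 lower, 162 by at least 2-fold. DESeq2 called 1211. With only the DKO groups in the fit limma called 1, Fcrls among the named genes, and with WT epithelium left out, an alternative added after seeing the data, 41, where the WT libraries with their lower spread no longer enter. The count was 975 without the sex covariate, 50 with age added and 622 with array weights, and all DKO cisplatin libraries were female. DKO cisplatin mice were 5 to 6 months old and DKO vehicle mice 6 to 8 months, so age is not well separated from the drug here. It was 171 and 227 without DKO vehicle replicates 1 and 5, and 130, 135, 71 and 1051 without DKO cisplatin replicates 1, 2, 3 and 4. Of 28 named genes past the threshold, 8 stayed past it whichever library was left out: Armc6, Armcx2, Cdkn1a, Dzip3, Enpep, Gclc, Pdlim2 and Wnt5a. The others were lost most often without DKO cisplatin replicate 3 (18 genes), 2 (14) or 1 (11), or DKO vehicle replicate 1 (15) or 5 (13), and replicates 2, 3, 4 and 6 of DKO vehicle and 4 of DKO cisplatin lost 2 to 7. Bbc3 and Pola1 were each lost in 8 of 10 omissions, and also with the sex term taken from tumours only, without the abundance filter, with equal totals, with RNA integrity or age added, by edgeR and without WT epithelium. With age added, Mdm2, Trp53inp1, Mt1, Mt2, Rrm2, Chil3, Clec4d, Enpep, Fcrls and Cx3cr1 did not pass either. With WT epithelium left out, Armc6 and Gclc, which held over every omission, did not pass. Neither did Mdm2, Trp53inp1, Mt1, Mt2, Rrm2, Chil3, Fcrls and Cx3cr1, among others.

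By camera, p53 targets (adjusted p = 0.000416), DNA replication (9.81e-05), NRF2 targets (0.0109) and immediate early genes (0.0109, median 0.77, 0 of 14 rising and 3 adjusted over the list alone) passed whichever library was left out. With an estimated correlation the adjusted p = 0.0567 for p53 targets and 0.814 for the other 3. Platinum transport (0.0300), mitosis (0.0210, down), ribosome biogenesis (0.0141, down) and endothelial markers (0.0159, down) lost the call without DKO cisplatin replicate 2 (0.0903 to 0.214), and interferon response (0.0109, up) without DKO cisplatin replicate 4 (0.443). For these 5 the adjusted p was 0.238 to 0.875 with an estimated correlation. Platinum transport was also lost without DKO vehicle replicate 1 (0.0974) or DKO cisplatin replicate 3 (0.0873), and mitosis without DKO cisplatin replicate 1 (0.0653) or DKO vehicle replicate 2 (0.0701) or 4 (0.0717). Endothelial markers were lost without DKO vehicle replicate 1 (0.0725) or 2 (0.0518) and ribosome biogenesis without DKO vehicle replicate 5 (0.119). Interferon response was lost without DKO vehicle replicate 1 (0.307) or 6 (0.0610) and without the sex covariate (0.0959).

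**Figure D4:**
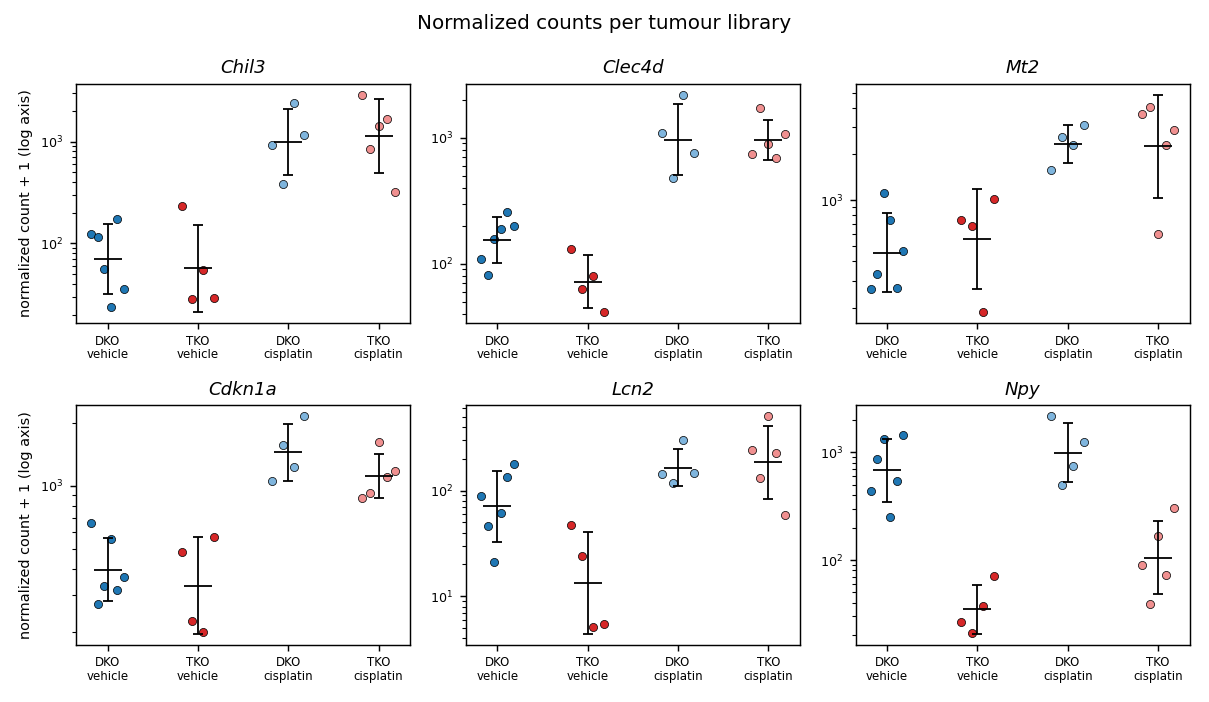
Normalized count + 1 (log axis) of Chil3, Clec4d, Mt2, Cdkn1a, Lcn2 and Npy in each library of the 4 tumour groups, where points are libraries and bars are the mean and SD of log2(normalized count + 1). Mean Cdkn1a was 416 and 368 with vehicle and 1497 and 1138 with cisplatin in DKO and TKO tumours.

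The same comparison in TKO tumours asks what cisplatin changes where Arf is floxed too. Genes of myeloid cells were among those that rose. Of 16 macrophage markers 3 rose (5 adjusted over the list alone; median 1.10): Cd14, a co-receptor for bacterial lipopolysaccharide, went from 258 ± 135 normalized counts (SD, n = 4) to 2471 ± 2057 (n = 5), and Mafb and Itgam rose too. Of 11 neutrophil markers 1 rose, Trem1 (7 adjusted over the list alone; median 2.53), and of 17 cytokines 1 rose, Cxcl2 (4 adjusted over the list alone). Named genes of the same kind were Chil3 (84.8 ± 97.7 to 1433 ± 973), Clec4d (77.6 ± 37.9 to 1021 ± 417), the chemokine gene Ccl6 (211 ± 215 to 2391 ± 1404) and Lcn2, lipocalin of neutrophils and epithelia (19.5 ± 19.8 to 232 ± 169.9). RNA integrity numbers were 9.8 to 10 with vehicle and 9 to 9.8 with cisplatin in these TKO tumours.

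Of the 22 p53 targets 2 rose (2 adjusted over the list alone): Cdkn1a went from 368 ± 185 (SD, n = 4) to 1138 ± 297 (n = 5), and Trp53inp1 from 418 ± 188 to 1167 ± 535. Abcc3, a drug efflux transporter, was the 1 platinum and thiol gene that rose (5 adjusted over the list alone), and Fos the 1 immediate early gene (5 adjusted over the list alone). Mt2 was at 658 ± 347 and 2698 ± 1366. None of 22 DNA replication genes passed (2 lower adjusted over the list alone; median -0.54, and -0.34 without TKO cisplatin replicate 2). No urothelial gene passed either (3 higher adjusted over the list alone). Their median was 1.30 but 0.57 without TKO cisplatin replicate 4 and 2.02 without replicate 1, so its size rested on single libraries, and TKO cisplatin replicate 4 alone had Krt5 at 14.8% of the WT mean. Named genes that fell included Klhl23 (122 ± 22.4 to 46.4 ± 17.3), Zfp111, Mypop, Faxc, Mthfsd, Slc39a10 and Myo9a. Klhl23 was also higher in TKO than in DKO vehicle tumours (32.7 ± 14.6 in DKO), and both calls use the same TKO vehicle libraries.

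Limma called 260 genes in TKO tumours, 196 higher and 64 lower, 149 by at least 2-fold. DESeq2 called 891. With only the TKO groups in the fit limma called 0 (1882 at an unadjusted p under 0.05, against 2571 with all samples), and with WT epithelium left out 65. EdgeR called 185. The count was 138 with samples scaled to equal totals, 84 with RNA integrity as a covariate and 46 with array weights. It was 397, 138, 115 and 33 without TKO vehicle replicates 1 to 4, and 105, 98 and 162 without TKO cisplatin replicates 2, 4 and 5. Of 25 named genes past the threshold, 6 stayed past it whichever library was left out: Ccl6, Cd14, Cdkn1a, Chil3, Clec4d and Lcn2. The others were lost most often without TKO vehicle replicate 4 (19 genes), 2 (12) or 3 (11), or TKO cisplatin replicate 2 (13), 4 (13) or 5 (11), and TKO cisplatin replicates 3 and 1 and TKO vehicle replicate 1 lost 8, 6 and 2. Mafb, Itgam and Mypop also did not pass without the sex covariate. With RNA integrity added, Abcc3, Faxc, Fos, Itgam, Klhl23, Mafb, Mthfsd, Myo9a, Mypop, Slc39a10 and Trem1 did not pass, and with array weights neither did Chil3, Clec4d and Trp53inp1. With WT epithelium left out, Abcc3, Fos, Itgam, Klhl23, Mafb, Mthfsd, Myo9a, Mypop, Slc39a10 and Zfp111 did not pass, among others.

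By camera, macrophages (adjusted p = 3.69e-07), neutrophils (3.96e-06), cytokines (0.00103) and the urothelial list (0.000183) were higher with cisplatin, and DNA replication (2.69e-05), ribosome biogenesis (0.000226), skeletal muscle (0.000226; 4 of 10 adjusted over the list alone) and protein folding (0.00173) lower. These 8 had an adjusted p = 0.455 with an estimated correlation. The p53 targets were higher (0.00355; adjusted p = 0.173 with an estimated correlation). All 9 passed whichever library was left out, although the median of the urothelial list fell to 0.57 without TKO cisplatin replicate 4. The mean log2 level of the skeletal muscle list was 6.78 and 7.58 in TKO vehicle replicates 2 and 3. It was 3.45 and 4.07 in replicates 1 and 4, and 3.33 to 3.74 in TKO cisplatin libraries. Omitting 1 library at a time keeps replicate 2 or 3 in the fit, so the omissions do not test this. Mitosis was lower (0.00328), and platinum transport (0.0148), basal (0.0259), FOXO target (0.0337), NRF2 target (0.0363) and immediate early (0.0382) genes higher, with an adjusted p of 0.173 to 0.562 with an estimated correlation. Each of these 6 lost the call without at least 1 library. These were TKO cisplatin replicate 2 (0.124) or TKO vehicle replicate 3 (0.0984) for mitosis, TKO vehicle replicate 2 (0.0558) for platinum transport, and TKO cisplatin replicate 4 (0.146) or TKO vehicle replicate 3 (0.0671) for the basal list. They were TKO cisplatin replicate 2 or 5 or TKO vehicle replicate 3 or 4 for FOXO targets (0.0614 to 0.126), and TKO cisplatin replicate 1 or 4 or TKO vehicle replicate 2 or 4 for NRF2 targets (0.175 to 0.229). For immediate early genes they were TKO cisplatin replicate 2, 3 or 4 or TKO vehicle replicate 2 or 3 (0.0656 to 0.206).

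The responses to cisplatin in the 2 genotypes were then set against each other. In the main fit, Chil3, Clec4d, Cdkn1a and Trp53inp1 rose in both. None of these genes passed in either genotype with only the groups compared. With WT epithelium left out, Chil3 and Trp53inp1 did not pass in DKO. Chil3, Clec4d and Trp53inp1 also did not pass in DKO with age added or in TKO with array weights. To correlate the responses across genes, the 2 sets of log2 fold changes came from a fit of the tumour groups alone, without WT epithelium and with sex as a covariate. Across 15308 genes, which are not independent replicates, they correlated at r = 0.357 (Spearman 0.405), and 66.8% of genes had the same sign. Random reassignments of the drug label within each genotype gave a median r of -0.0198 and a 95th percentile of 0.259 (one-sided permutation p = 0.0198). The correlation was 0.126 without TKO cisplatin replicate 1 and 0.208 without TKO vehicle replicate 3, both under that percentile.

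TKO and DKO tumours given cisplatin were compared to ask what floxed Arf alleles change under the drug. Adhfe1, an iron alcohol dehydrogenase, rose from 22.2 ± 4.9 normalized counts in DKO (SD, n = 4) to 114 ± 99.9 in TKO tumours (n = 5; log2 fold change 3.21, adjusted p = 0.0122), and Map7, a microtubule-associated protein, from 7.06 ± 3.18 to 89.9 ± 56 (3.95, adjusted p = 0.0139). Npy did not pass here (1157 ± 735 and 133 ± 105; log2 fold change -3.57, adjusted p = 0.111). These 2 were the only genes limma called, out of 1099 with an unadjusted p under 0.05, while edgeR called 1 and DESeq2 84. Limma called 0 with only these groups in the fit, with age added or with WT epithelium left out (489, 770 and 882 at an unadjusted p under 0.05), and 5 with array weights. Without the sex covariate Adhfe1 did not pass (log2 fold change 1.92, adjusted p = 0.424), in a comparison of females with mostly males, and by edgeR Map7 did not (adjusted p = 0.0636). It called 0 without DKO cisplatin replicate 2 or 3 or TKO cisplatin replicate 1, each of which lost both genes, and 4 without DKO cisplatin replicate 1 or TKO cisplatin replicate 5. No list member passed over all genes (1 adipocyte gene was higher adjusted over the list alone). By camera, adipocytes (0.00618), T and NK cells, macrophages and neutrophils (0.00781 each) were higher in TKO and interferon response (0.00781) lower, each with an adjusted p = 0.938 with an estimated correlation. Adipocytes passed whichever library was left out. The T and NK cell, macrophage and neutrophil calls were lost without DKO cisplatin replicate 2 (0.0969 to 0.795) or TKO cisplatin replicate 3 (0.0556 to 0.203), T and NK cells also without DKO cisplatin replicate 3 (0.142), and interferon response without DKO cisplatin replicate 4 (0.691) or TKO cisplatin replicate 1 (0.212) or 2 (0.0595). Without the sex covariate the macrophage and interferon calls were lost (0.0679 and 0.595).

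The difference between the responses of the 2 genotypes was tested as an interaction of drug and genotype. Limma called 0 genes, with 523 at an unadjusted p under 0.05 and a smallest adjusted p of 0.120, for Cd300lh, a receptor of myeloid cells. It called 1 gene without DKO vehicle replicate 4 and 2 with a pseudocount of 5. EdgeR called 0 with 705 at an unadjusted p under 0.05, and DESeq2 called 15 with 890. Lcn2 and Pdlim2 were among the named genes and did not pass (interaction of 3.79 and 1.45 on the log2 scale).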

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

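Among the tests in this part, those on the sex labels, on the library of TKO cisplatin replicate 4 and on the share of tumour cells, the omission of single libraries from the RNA integrity test, the limit of a mean of 10 or more for single samples standing apart, and the list medians without single libraries were chosen only after the result was seen.

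In WT epithelium all 5 libraries had Ddx3y against their sex label, and none of 19 tumours did. An admixture of tissue of the other sex is argued against, since the lower of Xist and Ddx3y reached no more than 0.233% of its level in the WT libraries that express it. An exchange with tumour libraries is argued against as well, since the lowest WT value of Upk2 was 211 times the highest tumour value, and so is another order of the columns within the group, since 3 WT libraries lacked Ddx3y where 2 are labelled female. Entries reversed for the whole group, with 5 of 5 libraries against their label, may account for it as a hypothesis. A swap of the sex entries with samples outside the series stays open, and no biological explanation was tested.

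TKO cisplatin replicate 4 had more epithelial transcripts than the other tumours, with 20 of 32 urothelial and basal genes above every other tumour library. The shares of the WT mean in these 20 ran from 0.390% for Upk2 and 0.427% for Upk3a to 14.8% for Krt5, 18.7% for Krt15, 88.8% for Col17a1 and 129% for Pkp1. Admixed epithelium with the makeup of the WT libraries is argued against, since the 75th percentile of the share was 5.26 times the 25th over the 32 genes, which include Cdh3, Cd44 and Egfr at 705%, 270% and 185% of the WT mean, and 7.94 times over the 20, where the highest such ratios in a WT library were 1.35 and 1.40 (comparisons set after the values were seen). Cells of the other sex may be present, since Xist (2912) was 6.05 times the highest of the other males and above the lowest female-labelled tumour (1997), while Ddx3y (796) lay within the range of other males (601 to 1409). A tumour with basal features, basal cells from another mouse and Xist made by male tumour cells stay open, and no biological explanation was tested.

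Neutrophil and macrophage genes were higher in TKO tumours after cisplatin, with a median log2 fold change of 1.62 over 27 genes, 4 of them past the threshold. Lower RNA integrity in the TKO cisplatin libraries as the whole cause is argued against, but only weakly. With RNA integrity in the fit the median was 1.003 times that without it (0.789 to 1.08 with single libraries left out). The slope for RNA integrity was shared by all groups, WT epithelium included. Within TKO tumours, integrity hardly overlapped between treatments (9.8 to 10 with vehicle, 9 to 9.8 with cisplatin), so it is not well separated from the drug there. Of the 4 genes only Cd14 then passed, while the log2 fold changes of Itgam, Mafb and Trem1 went from 1.67, 1.503 and 2.69 to 1.70, 1.23 and 2.13, their standard errors from 0.428, 0.371 and 0.575 to 0.496, 0.410 and 0.611, and their adjusted p to 0.115, 0.163 and 0.109, so RNA integrity stays open as a part of the change in single genes. Whether a lower share of tumour cells raised every other cell type alike was also tested. The values do not decide it, since only some of the cell type lists moved apart from the myeloid lists. The 2 myeloid lists exceeded the endothelial, smooth muscle and nerve lists by 1.90 ± 0.594 with cisplatin and 0.257 ± 1.34 with vehicle (SD, n = 5 and 4). The difference was 1.64 (exact two-sided permutation p = 0.0159). The myeloid lists exceeded all 8 other cell type lists by 2.47 ± 0.471 and 0.973 ± 0.788 (exact two-sided permutation p = 0.0238). Without TKO vehicle replicate 4 the first difference fell to 0.986 (exact two-sided permutation p = 0.0714), and that against all 8 was 1.18 (exact two-sided permutation p = 0.0357). Without TKO cisplatin replicate 1, 2, 3 or 4 neither difference passed (exact two-sided permutation p = 0.0571 for both in each omission). Taken singly, T and NK cells (exact two-sided permutation p = 0.373), B and plasma cells (0.984), adipocytes (0.452) and fibroblasts (0.0635) did not move apart from the myeloid lists. Endothelial (exact two-sided permutation p = 0.0238), smooth muscle (0.0397), nerve and glia (0.0238) and skeletal muscle lists (0.0159) did. The difference was largest for skeletal muscle (3.58). The mean log2 level of that list was 6.78 and 7.58 in TKO vehicle replicates 2 and 3, and 3.45 and 4.07 in replicates 1 and 4. More myeloid cells, or a change in those present, may underlie the pattern as hypotheses that stay open, and camera did not pass with an estimated correlation (0.455 for both lists).

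By the test of the interaction, 9 lists differed between the genotypes in their response to cisplatin by camera with a preset correlation, and none with an estimated one or by fry. The response in TKO exceeded that in DKO for neutrophils (adjusted p = 2.03e-07, median 3.23), macrophages (4.86e-06, median 1.004), endothelial cells (7.89e-05, median 1.17), B and plasma cells (0.00285, median 2.16) and adipocytes (0.00439, median 2.12), each with adjusted p = 0.536 with an estimated correlation. It also exceeded it for T and NK cells (0.000859, median 1.49) and urothelial differentiation (0.00429, median 0.93), each with adjusted p = 0.731 with an estimated correlation. It was lower for skeletal muscle (4.29e-06, median -2.16; adjusted p = 0.536 with an estimated correlation) and interferon response (0.000283, median -0.999; adjusted p = 0.826 with an estimated correlation). The urothelial call was lost without TKO cisplatin replicate 4 (0.175) or TKO vehicle replicate 3 (0.181), the B and plasma cell call without TKO vehicle replicate 3 (0.111), and the adipocyte call without DKO vehicle replicate 5 (0.148). The interferon call was lost without DKO vehicle replicate 1 (0.142), TKO vehicle replicate 4 (0.122) or DKO cisplatin replicate 4 (0.217). Without the sex covariate the adipocyte (0.0602) and interferon (0.105) calls were lost. The mean log2 level of the skeletal muscle list was 6.78 and 7.58 in TKO vehicle replicates 2 and 3 and 6.09 in DKO cisplatin replicate 1. It was 2.68 to 5.12 in the other tumour libraries. With single libraries left out the medians were 2.09 to 3.94 for neutrophils, 0.42 to 1.28 for macrophages, 0.70 to 1.502 for endothelial cells, 1.46 to 3.51 for B and plasma cells, 1.38 to 2.79 for adipocytes, 0.84 to 2.59 for T and NK cells, 0.36 (without TKO cisplatin replicate 4) to 1.69 for the urothelial list, -3.02 to -1.33 for skeletal muscle and -1.997 to -0.30 for interferon response. As many as 9 lists passed in 63 of 100 splits of the samples, up to 16, so chance is not excluded.

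Single samples stood apart from the rest of their group, by a gap to the nearest sample that took a large part of the group's range, in 11 of 182 pairs of a named gene and a group with a mean of 10 or more (6.04%), where chance gives about 1 in 20. Gap and range were taken on the log2 scale, while the levels given are normalized counts. In TKO cisplatin replicate 3, Cdkn2a was low (1038 against 2547 to 3238 normalized counts; gap 0.789 of the range), Trp53 high (428 against 157 to 199; 0.766), Fpr2 high (227 against 93.9 to 107; 0.849) and Ugt1a6a low (61 against 97.1 to 116; 0.722). Clstn1 was low in DKO vehicle replicate 6 (400.1 against 812 to 1071; 0.718). The gap was 0.922 for Fpr2, high in TKO vehicle replicate 1, and 0.895 for Mypop, high in TKO vehicle replicate 4. It was 0.9499 for Slc39a10, high in TKO vehicle replicate 2, and 0.868 for Yy1, high in DKO cisplatin replicate 2. Atp10d was low in TKO cisplatin replicate 1 (0.730) and Luc7l in DKO vehicle replicate 5 (0.674).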

How the results depend on the processing

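The sex term from tumours only and the fit without WT epithelium were tests chosen only after the result was seen. The counts of genes in tumours against WT epithelium stayed within 1.5 times under every setting run for them and every omission (8955 to 9548 for DKO and 8059 to 8345 for TKO with single libraries left out), but age, which separates WT mice from those with tumours, was not run as a covariate there, and genes past the threshold kept their sign in every setting. Counts among tumours moved, and the cause was not tested unless given. TKO against DKO vehicle (13 genes) had 7 with a filter of 50, 6 with only the groups compared, 3 with array weights, 204 by DESeq2 and 2 to 37 with single libraries left out. Cisplatin against vehicle in DKO (371) had 975 without the sex covariate, 1 with only the groups compared, 50 with age, 622 with array weights, 1211 by DESeq2, 41 without WT epithelium and 71 to 1051 with single libraries left out. In TKO (260) it had 0 with only the groups compared, 138 with equal totals, 84 with RNA integrity, 46 with array weights, 891 by DESeq2, 65 without WT epithelium and 33 to 397 with single libraries left out. TKO against DKO with cisplatin (2) had 0 with only the groups compared, with age or without WT epithelium, 5 with array weights, 1 by edgeR, 84 by DESeq2 and 0 to 4 with single libraries left out. The interaction (0) had 2 with a pseudocount of 5, 15 by DESeq2 and 0 to 1 with single libraries left out. Fits with only the groups compared rest on fewer samples and on the wider spread of tumours. The agreement of the cisplatin responses was 0.126 to 0.419 with single libraries left out. Of 76 list calls, 1 held with an estimated correlation, 35 by fry, 71 without the sex covariate and 76 under quantile normalization; 749 of 822 held over omissions of a library. Some values that passed in no setting changed sign, and the cause was not tested. On the log2 scale, Cdkn2a in TKO against DKO vehicle was -0.19 with array weights and -0.0592 to 0.404 with single libraries left out (below 0 without DKO vehicle replicate 6 or TKO vehicle replicate 4). In the TKO response it was 0.54 with array weights and -0.268 to 0.195 with single libraries left out (above 0 without TKO vehicle replicate 3 or 4 or TKO cisplatin replicate 3). Pten in TKO against DKO with cisplatin was -0.27 with only the groups compared, -0.0353 with the sex term from tumours only or without WT epithelium, and -0.0599 to 0.223 with single libraries left out (below 0 without TKO cisplatin replicate 5). Trp53 was -0.00506 in the DKO response with age. In the interaction it was -0.00848 with RNA integrity and -0.0300 to 0.346 with single libraries left out (below 0 without DKO cisplatin replicate 2 or TKO cisplatin replicate 3). A depth of 8958512 to 13337322 reads limits genes near the floor of 3 reads over a group.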

Other observations

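All tests in this part were chosen before the result was seen, except the comparison with other stretches of genes around the neighbours of Cdkn2a, the adjustment of the shares of splits and the list medians with single libraries left out.

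Several gene groups did not differ from other genes by camera in vehicle tumours against WT epithelium, although single members changed and fry, which does not compare with other genes, called some of them. Of 23 genes for repair of crosslinks and damaged bases, 6 rose and 6 fell in each genotype: in DKO, Rad51 and Brca1 of homologous recombination rose by 4.04 and 2.45 on the log2 scale and Xpc, which senses damage, fell by 1.33 (camera adjusted p = 0.754 in DKO and 0.647 in TKO). Of 17 genes of platinum transport and thiols, 8 fell and 3 rose in DKO, and 7 fell and 3 rose in TKO (0.0853 and 0.0617; fry adjusted p = 9.18e-11 and 3.09e-10, down). Gstm1, a glutathione transferase, went from 93070.5 ± 25857 (SD, n = 5) to 411 ± 113 (n = 6) and 427 ± 228 (n = 4). Of 10 hedgehog pathway genes, 7 fell in each genotype (0.147 and 0.0875; fry adjusted p = 1.02e-05 and 1.85e-05), among them the ligand gene Shh, with no reads in either (at least 7300-fold lower in DKO and at least 4590-fold in TKO). Of 18 genes of hypoxia and glycolysis, 7 rose in DKO and 6 in TKO (5 adjusted over the list alone in each; 0.0793 and 0.0529). FOXO targets had 7 of 14 lower and 1 higher in DKO and 6 lower and 1 higher in TKO (0.227 and 0.459), apoptosis regulators 7 of 19 higher and 5 lower in DKO and 5 higher and 6 lower in TKO (0.670 and 0.681), and immediate early genes 3 of 14 higher and 4 lower in DKO and 3 higher and 5 lower in TKO (0.943 and 0.949). Fry also called hypoxia (0.0249 in DKO and 0.0286 in TKO) and apoptosis regulators (0.0343 and 0.0460) in both genotypes and FOXO targets in DKO (0.000970). Except where given, counts in these lists were the same adjusted over the list alone.

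Lists of lymphocyte markers did not pass as higher in vehicle tumours: 1 of 17 T and NK cell genes rose in DKO and 0 in TKO (camera adjusted p = 0.943 and 0.853, and so for the lists that follow), and 1 of 6 B and plasma cell genes in DKO (0 adjusted over the list alone) and 0 in TKO (0.782 and 0.949), although the median of the B and plasma cell list was 0.83 on the log2 scale in DKO (0.64 to 1.11 with single libraries left out) and -0.21 in TKO. In TKO vehicle libraries the mean log2 level of the B and plasma cell list ran from 1.35 to 4.56, on both sides of the 2.31 to 3.68 in WT epithelium. Antigen presentation had 2 of 16 genes higher in each genotype and 1 lower in DKO (0 lower adjusted over the list alone; 0.851 and 0.958). Endothelial markers had 3 of 13 higher and 2 lower in DKO (0 and 1 adjusted over the list alone), and 1 higher and 3 lower in TKO (1 and 2 adjusted over the list alone; 0.851 and 0.396). Smooth muscle had 5 of 11 higher and 2 lower in DKO and 6 higher in TKO (0.225 and 0.0592), and skeletal muscle 2 of 10 higher and 1 lower in DKO and 7 higher and 1 lower in TKO (0.558 and 0.0592). Nerve and glia had 2 of 9 higher and 5 lower in DKO, and 2 higher and 1 lower in TKO (2 and 0 adjusted over the list alone; 0.851 and 0.647), and adipocytes 3 of 6 lower in each (0.178 and 0.179). Of these lists fry called smooth muscle (0.0249 in DKO and 0.00250 in TKO) and adipocytes (0.00148 and 0.00449) in both genotypes and skeletal muscle in TKO (0.00672). Where no other count is given, these were the same adjusted over the list alone. The median and the test differed in sign for antigen presentation in both genotypes, for T and NK cells in DKO, and for nerve and glia and immediate early genes in TKO. Of the list of male accessory glands 0 genes were measured and of that of red blood cells 2, neither of which passed, so these lists were not tested. After cisplatin, 2 apoptosis regulators and 1 FOXO target rose in DKO tumours and 1 gene for repair rose and 1 fell. In TKO tumours 1 apoptosis regulator rose and 1 fell.

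Other splits of the same samples were fitted for every count, 100 for each with the real one included. For genes, chance is argued against where only the real split was as large. These were DKO vehicle against WT epithelium (9565 genes, highest other split 8427, 1 split as large) and TKO vehicle against WT epithelium (8722, highest other 6784, 1). The others were cisplatin in DKO (371, highest other 100, 1) and cisplatin in TKO (260, highest other 86, 1). Each share was 0.01, the smallest that 100 splits can give, and 0.035 adjusted over the 14 counts. The cisplatin counts fell as low as 71 in DKO and 33 in TKO with 1 library left out. They were 1 and 0 with only the groups compared, and splits were not run for those fits. For TKO against DKO vehicle (13, highest other 32) 4 splits were as large, a share under 0.05 alone and of 0.112 adjusted over the 14 counts, so that chance is not firmly excluded. Chance is not excluded for TKO against DKO with cisplatin (2, highest other 387; 8). For the interaction the real count is 0, so that all 100 splits are as large whatever the data, and the splits say nothing of chance (highest other 732). The splits with 387 and 732 genes may point to a structure of the samples, and what it is was not tested. For the number of lists past the threshold by camera chance is excluded in no comparison: the real and highest other values were 16 and 17 for DKO vehicle against WT epithelium (5 splits as large), 15 and 18 for TKO vehicle (25), 7 and 15 for TKO against DKO vehicle (48), 9 and 13 for cisplatin in DKO (17), 15 and 20 for cisplatin in TKO (25), 5 and 16 for TKO against DKO with cisplatin (98), and 9 and 16 for the interaction (63).

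A hypothesis tested was that genes near Cdkn2a differ between TKO and DKO vehicle tumours because of DNA linked to the floxed Arf allele. Among the 50 tested genes on each side of Cdkn2a in the order of the RefSeq annotation, 100 in all, 17 had an unadjusted p under 0.05, against 9.30% of all other genes, a ratio of 1.83 (one-sided Fisher's exact p = 0.0110), 15 of the 17 were higher in TKO, and 0 passed the adjusted threshold. Neighbouring genes can share regulation, however, and 11 of 133 other stretches of 100 genes held as many (a share of 0.0896 with the real one), so linkage and ordinary clustering cannot be told apart for these genes.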
